A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

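RNA was measured in 4 libraries of Saccharomyces cerevisiae, 2 from uninduced and 2 from induced cultures. Per the labels' protocols, RNA was extracted with hot acid phenol, libraries were made with a stranded mRNA kit (TruSeq) and sequenced on a HiSeq instrument. Libraries were assigned to groups by the treatment given in their labels, and table columns to libraries by their names.

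The authors deposited 1 table for the series, with 6782 gene rows. TopHat2 version 2.0.13, HTSeq and edgeR, with the genome builds sacCer3 and R64, are named in the submitters' processing notes, without the role of each. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. Reads of a gene and of a gene on the opposite strand at the same place may therefore have been mixed, and the handling of reads shared by near-identical paralogs is unknown. Per the file headers, the values per library are CPM, read counts scaled by library size; the deposited signal is a normalized one, since the column sums were 1026833 and 1041888 for the uninduced libraries and 949572 and 945865 for the induced libraries. The deposited table also holds the authors' log2 fold change (base taken from the values), raw p-value and FDR-adjusted p-value for induced against uninduced. These columns were used as a description only.

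Within each column every value was a whole multiple of 1 step, the worth of 1 read, so that whole reads could be recovered for 100% of values in all 4 columns within 0.001 reads. The step of uninduced library 2, 0.1002 CPM, lies close to a round decimal fraction, so a whole multiple there is weaker evidence for reads than in the other columns, although its values are not rounded. Recovered reads summed to 10397606 to 15582338 per library. The size used by the authors' scaling was 0.974 and 0.960 times this sum in the uninduced libraries and 1.05 and 1.06 times in the induced libraries. A count of 3 reads, taken as the floor, corresponded to 0.193 to 0.301 CPM. The 10 highest genes held 8.96% to 9.35% of reads, and SED1 was highest in each library.

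The main test was limma (version 3.58.1, R 4.3.3) on log2(CPM + 1), with group as the single term, an intensity trend in the variance, two-sided tests and Benjamini-Hochberg adjustment over the genes kept. Genes with a mean under 1 CPM over the 4 libraries were left out, which removed 745 rows. A call is an adjusted p under 0.05. Levels are given as mean ± SD of 2 libraries and a ratio of means is taken on the CPM scale. The unit differed in name from the plain CPM assumed before the data were examined, and the planned test for CPM was used unchanged.

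A set of 34 gene lists was fixed before the data were examined, from general knowledge of yeast pathways. Each list was tested against all other genes with camera (limma), with a preset inter-gene correlation of 0.01 and adjustment over the 34 lists, and again with the correlation estimated from the data. The estimated run rests on the few residual degrees of freedom of 4 libraries, so few lists could pass it. The tool fry was run beside it. Each list also has its count of members called over all genes and adjusted over the list alone. A further 10 lists were chosen after seeing the data and are used in the closing observations only.

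Genes named in the text followed a rule fixed before the data were examined. It takes the 10 called genes with the largest rise and the 10 with the largest fall, among those with a mean of 5 CPM or more and no overlap between groups. It adds from each list the 3 called members with the largest change, or the largest member where none was called. It always takes LEU2, GAL1, STE24, KAR2, HAC1, HSF1, SSA4, HSP104, RPN4, PDR5 and HSP12. Together these are 127 genes, of which 1 is not reported here. Members named for falling outside a list's main direction or its call (CNE1, SRP72, SSH1, RPL41A, RPL41B, MFA1, MFA2, GAL80, GCY1, MTH1), the members misnamed by a pattern (RPP1, MRP8) and VRP1 were chosen after their values were seen.

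The fits were tested on simulated reads drawn from the means and sizes of these 4 libraries, with 200 genes, and the genes of a further list, changed by known amounts among 6026 genes fitted. For induced against uninduced, limma recovered 92.5% of genes changed by 0.5 on the log2 scale, 89.6% of those changed by 1 and 98.5% of those changed by 2, and 5.75% of its calls were false. On the same simulation edgeR had 7.36% false calls and DESeq2 0.490%, and camera called 0 of 12 lists drawn from unchanged genes. Simulated genes were drawn independently of each other, so these lists cannot test the preset correlation. Few genes were changed in the simulation, against 72.7% called in the data, so the false-call shares do not carry over.

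Replicates were compared before averaging. A chi-square per degree of freedom of 4.72 for the uninduced pair and 5.04 for the induced pair, over 5993 genes, shows only that the spread within a pair exceeded sampling noise. That the libraries are separate replicates rests on the design text. Pearson's r across genes was 0.997 within both pairs and 0.933 to 0.938 between groups; genes are not independent replicates.

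Alternatives planned before the data were examined were pseudocounts of 0.25 and 5 CPM, no filter and a minimum of 10 CPM, median-of-ratios scaling, quantile normalization, no variance trend, a robust variance prior, the replicate number as a block, leaving out each library in turn, and edgeR (version 4.0.16) quasi-likelihood and DESeq2 (version 1.42.0) tests on the recovered reads. On those reads edgeR called 4413 genes and DESeq2 3822. Added after seeing the data were scaling to total reads, a block with crossed replicate numbers, a limma test against a 1.2-fold change, lists without members shared with the unfolded protein response list, and the ribosomal lists without RPP1 and MRP8. Coordinates, coding lengths and GC content came from an annotation of the R64 build, the build named in the processing notes, in which 5979 rows were matched by locus tag. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for matching, checks and figures.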

Results

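Budding yeast of the W303 background carried a single copy of a construct named 6xIAPP, integrated at LEU2 behind a promoter that estradiol switches on. IAPP is islet amyloid polypeptide, a peptide hormone of pancreatic beta cells that forms amyloid. The series title frames the experiment as an assay of 6xIAPP toxicity, and the comparison asks which mRNAs changed when the construct was induced. 2 cultures received the solvent DMSO and 2 received 100 nM estradiol, each for 6 h in log phase. The design text calls the 2 cultures per arm biological replicates. Polyadenylated RNA was sequenced, and the reads recovered from the authors' values came to 15582338 and 10397606 in the uninduced libraries and 11694161 and 14724917 in the induced libraries. Levels are normalized CPM, read counts scaled by library size, as mean ± SD with n = 2 libraries per group. Log2 fold changes are induced minus uninduced on the log2(CPM + 1) scale, as value ± SE, and this scale understates the change of low genes. Coordinates are gene spans in the R64 build. No library with estradiol and without the IAPP gene was analysed, so the inducer and the construct changed together.

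The transcriptome shifted broadly. Of 6037 genes kept, 4387 (72.7%) changed in the limma test, 2152 higher and 2235 lower in the induced libraries. A change of at least 2-fold was found for 861 of them, 425 higher and 436 lower. In 5190 genes (86.0%) both induced libraries lay on the same side of both uninduced libraries, against 33.3% by chance. Replicates lay close together: over 5017 genes with a mean of 20 CPM or more, the log2 difference within a pair had an SD of 0.12 (uninduced) and 0.11 (induced). The authors' deposited table called 2606 genes at its own adjusted p under 0.05, 1287 higher and 1319 lower; of the 2530 among the genes kept, 2529 were called here in the same direction and 0 in the opposite one. The other 1858 of the 4387 calls made here were not called in the authors' deposited table. With libraries scaled to their total reads, the median of all genes moved to 0.12 on the log2 scale and 60% of calls were higher, against 49.1% with the authors' scaling. Tested against a 1.2-fold change, 2685 genes passed, 1286 higher and 1399 lower.

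The largest rise was in ULI1 (chromosome VI, 205748 to 206257), a gene induced in the unfolded protein response, which went from 14.1 ± 0.872 to 972 ± 7.13 CPM (6.01 ± 0.06, adjusted p = 2.15e-15), a ratio of means of 68.7. It was followed by AMF1, an ammonium transporter (3.78 ± 0.0365 to 116 ± 3.56 CPM), OPI9 (2.74 ± 0.519 to 76.6 ± 5.23 CPM), SLZ1, a subunit of the mRNA methylation complex (2.70 ± 0.56 to 58.5 ± 3.46 CPM), and RTA1, a membrane protein linked to drug resistance (2.94 ± 0.239 to 53.1 ± 4.63 CPM). OPI9 is a dubious open reading frame that overlaps VRP1, and VRP1 itself, looked up after these values were seen, went from 453 ± 25.2 to 626 ± 73.4 CPM (0.46 ± 0.07). The other 5 of the top 10 were YHR033W (3.74), the formin BNR1 (3.60), the sulfate permease SUL1 (3.57), DIA3 (3.51) and BNA5, the kynureninase of NAD synthesis (134 to 1528 CPM, 3.50). HPF1 (chromosome XV, 28703 to 31606), a cell wall mannoprotein, fell most, from 449 ± 17.0 to 14.7 ± 1.77 CPM (-4.84 ± 0.08, adjusted p = 1.62e-13). RPI1, a regulator of cell wall genes, fell from 176 ± 0.389 to 9.23 ± 2.03 CPM, the mitochondrial protein gene FMP48 from 125 ± 7.96 to 6.91 ± 0.128 CPM and the membrane protein gene YRO2 from 557 ± 32.3 to 37.9 ± 3.49 CPM. Then came YDR222W (-3.80), the alpha-factor gene MF(ALPHA)2 (-3.52), ZPS1 (-3.25), the proline permease PUT4 (-3.09), YDR134C (-3.07) and the acid phosphatase PHO3 (-3.04). Adjusted p was at most 9.65e-10 for these 20 genes.

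**Figure D1:**
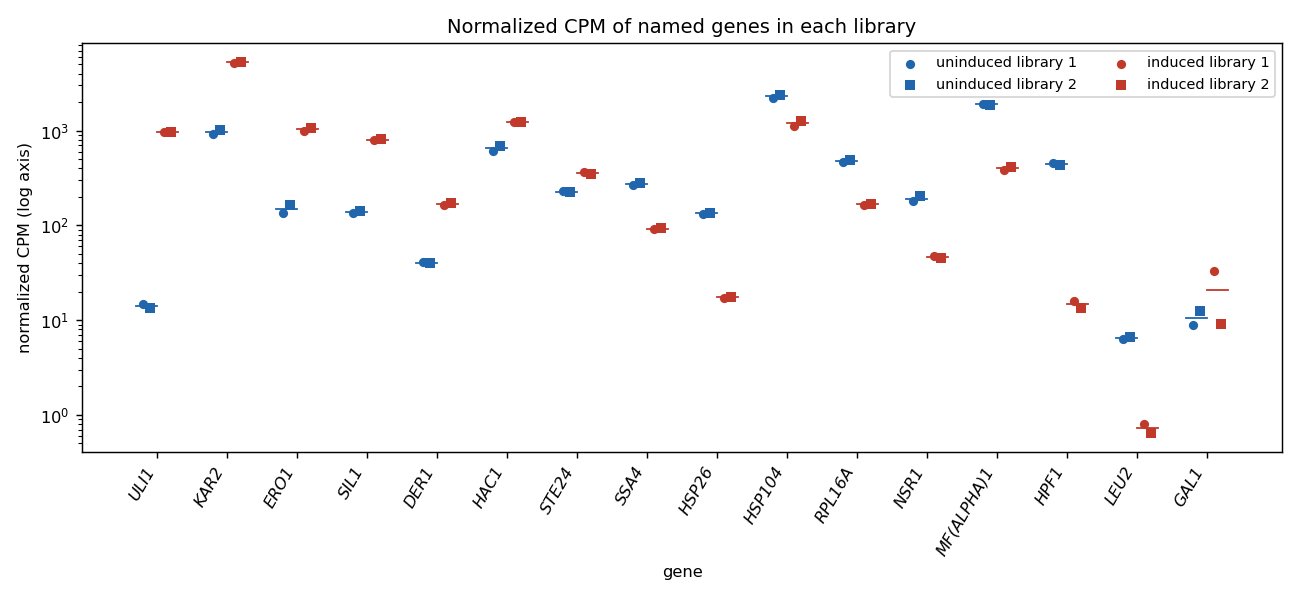
Normalized CPM on a log axis for 16 genes, with 1 point per library (blue, uninduced; red, induced; circles, library 1; squares, library 2) and short lines at the group means. The libraries of a pair lie close together for all genes shown except GAL1, where induced library 1 is at 33.0 CPM and induced library 2 at 9.06 CPM.

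Genes of the unfolded protein response, which expands the folding capacity of the endoplasmic reticulum (ER), rose together. Of 21 members tested, 20 rose and 0 fell, with a median log2 fold change of 1.32. By camera the unfolded protein response list stood above other genes at adjusted p = 9.01e-10, but had adjusted p = 0.432 with an estimated correlation. Here and for each list below, the estimated run rests on few residual degrees of freedom, so few lists could pass it. Its lost calls do not measure correlation between genes. ERO1, the thiol oxidase of the ER, went from 150.0 ± 20.5 to 1031 ± 63.1 CPM (2.78 ± 0.08), and SIL1, a nucleotide exchange factor, from 138 ± 5.15 to 798 ± 13.1 CPM (2.53 ± 0.05). KAR2 (chromosome X, 381327 to 383375), the Hsp70 chaperone of the ER lumen, went from 967 ± 68.5 to 5277 ± 53.4 CPM (2.45 ± 0.07, adjusted p = 1.64e-11). HAC1 (chromosome VI, 75179 to 76147, a span that holds the intron removed by Ire1), which encodes the transcription factor of the response, rose from 653 ± 61.6 to 1243 ± 2.51 CPM (0.93 ± 0.06); gene totals cannot tell its spliced from its unspliced form. CNE1, the calnexin homologue, was the member that passed in neither direction (0.01, adjusted p = 0.87). In the list of ER-associated degradation, which sends misfolded ER proteins to the cytosol, 15 of 18 members rose and 1 fell, with a median of 0.35. The degradation list had camera adjusted p = 0.000282 for standing above other genes, and adjusted p = 0.432 with an estimated correlation. DER1 went from 40.6 ± 1.13 to 169 ± 7.39 CPM, DFM1 from 209 ± 1.48 to 518 ± 7.47 CPM and HRD3 from 136 ± 3.10 to 321 ± 7.42 CPM. DER1 also stands in the unfolded protein response list.

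Proteasome genes rose by smaller steps, in 32 of 33 members with 0 lower and a median of 0.38. The proteasome list stood above the other genes tested (camera adjusted p = 5.8e-07), a call lost at adjusted p = 0.432 with an estimated correlation. The highest values were in RPN13 (0.58 ± 0.06), RPT5 (0.57 ± 0.05) and RPT6 (0.57 ± 0.05), and RPN4, the transcription factor of proteasome genes, went from 195 ± 10.4 to 250.4 ± 3.22 CPM (0.36 ± 0.05, adjusted p = 4.99e-05). Against a 1.2-fold change RPN4 did not pass (adjusted p = 0.103, with a range over its alternatives of 2.38e-07 to 0.103), and in the authors' deposited table its adjusted p was 0.13. Among genes of the ER translocon and of protein targeting to it, 15 of 28 rose and 6 fell, with a median of 0.24. By camera the ER translocon list stood above other genes at adjusted p = 0.0494, but had adjusted p = 0.432 with an estimated correlation. SEC62 (197 to 431 CPM), SEC72 (106 to 231 CPM) and the signal peptidase subunit SPC2 (70.0 to 145 CPM) rose most, while SRP72 of the signal recognition particle (-0.71) and SSH1 of the alternative translocon (-0.71) fell most. STE24 (chromosome X, 642007 to 643368), an ER membrane protease that clears blocked translocons, went from 228 ± 1.91 to 357 ± 8.39 CPM (0.65 ± 0.05, adjusted p = 7.62e-08). The translocon list lost its call when SEC61 and SPC2, shared with the unfolded protein response list, were left out (median 0.10, adjusted p = 0.118), and in 6 planned settings, the estimated correlation included (range of adjusted p over its alternatives against other genes, 0.0112 to 0.432).

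Cytosolic chaperones moved the other way. Of 22 genes in the Hsf1 list, which holds chaperone genes and some others, 15 fell and 6 rose, with a median of -0.47. The Hsf1 list had camera adjusted p = 0.0201 for standing below other genes, and adjusted p = 0.649 with an estimated correlation. The small heat shock protein gene HSP26 fell from 134 ± 1.39 to 17.4 ± 0.421 CPM (-2.88 ± 0.07), BTN2, an aggregate-sorting factor, from 148 ± 30.1 to 38.6 ± 5.70 CPM, and SSA4 (chromosome V, 364589 to 366517), an inducible Hsp70, from 274 ± 6.82 to 92.4 ± 1.45 CPM (-1.56 ± 0.05). The disaggregase HSP104 (chromosome XII, 88623 to 91349) fell from 2319 ± 117 to 1192 ± 112 CPM (-0.96 ± 0.07; -0.63 after quantile normalization). HSF1, the gene of the heat shock factor, rose from 244 ± 15.9 to 361 ± 18.9 CPM (0.56 ± 0.06). Quantile normalization ended the call of this list (median -0.25, adjusted p = 0.107, with a range of 0.00454 to 0.649 over its alternatives). Among 9 mitochondrial chaperone genes, 6 fell and 1 rose, and the list was not called (median -0.43). The mitochondrial chaperone list did not stand apart from other genes (camera adjusted p = 0.0961, and adjusted p = 0.432 with an estimated correlation). HSP60 fell from 986 ± 25.5 to 549 ± 0.226 CPM, HSP78 from 947 ± 56.2 to 572 ± 36.3 CPM and MDJ1 from 275 ± 2.47 to 176 ± 5.38 CPM.

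Of 26 general stress genes driven by Msn2 and Msn4, 15 fell and 6 rose (median -0.19). By camera the Msn2/4 list stood below other genes at adjusted p = 0.0494, but had adjusted p = 0.558 with an estimated correlation. YGP1, a secreted glycoprotein gene, fell from 1383 ± 38.0 to 199.6 ± 11.1 CPM, SPI1 from 743 ± 2.51 to 166 ± 1.49 CPM and DDR2 from 185 ± 43.1 to 54.0 ± 10.9 CPM, whereas HSP12 rose from 998 ± 89.0 to 1436 ± 52.0 CPM (0.53 ± 0.07; 0.83 after quantile normalization). This list lost its call in 10 alternatives: without induced library 1 it had adjusted p = 0.0758, after quantile normalization its median was 0.02 (adjusted p = 0.665), and adjusted p over its alternatives ran from 0.00126 to 0.665. In the oxidative stress list 9 of 18 genes rose and 5 fell, and the list was not called (median 0.15). The oxidative stress list did not pass camera, with adjusted p = 0.198, and adjusted p = 0.467 with an estimated correlation. TSA1, a peroxiredoxin gene, rose from 1032 ± 20.4 to 2296 ± 68.7 CPM and OYE3 from 15.1 ± 1.21 to 40.9 ± 0.246 CPM, while SRX1, the sulfiredoxin gene, fell from 9.54 ± 0.819 to 3.92 ± 0.0882 CPM. Pleiotropic drug resistance genes split, 3 of 12 higher and 5 lower, with a median of -0.11 (0.02 with total-count scaling) but a mean of 0.21. Drug resistance genes as a list did not stand apart from other genes (camera adjusted p = 0.761, and adjusted p = 0.821 with an estimated correlation). Besides RTA1, RSB1 rose (1.03 ± 0.11) and TPO1 fell (-1.05 ± 0.08), and the transporter gene PDR5 was at 151 ± 10.2 CPM uninduced and 161 ± 7.10 CPM induced (0.10 ± 0.06, adjusted p = 0.169). PDR5 passed as higher without uninduced library 1 (0.16, adjusted p = 0.0322) and with total-count scaling (0.22, adjusted p = 0.00692), and its adjusted p ran from 0.00692 to 1 over its alternatives.

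Genes of ribosomal proteins and of ribosome biogenesis fell almost as a block. The list of cytosolic ribosomal protein genes, drawn by a name pattern, held 139 genes, of which 137 fell and 0 rose, with a median of -1.02. By camera the cytosolic ribosomal list stood below other genes at adjusted p = 1.02e-30, but had adjusted p = 0.432 with an estimated correlation. The pattern took in RPP1 (43.4 to 26.7 CPM, -0.68), a subunit of RNase P and not a ribosomal protein. Without it 136 of 138 genes fell and 0 rose, with a median of -1.03 (camera adjusted p = 1e-30, and adjusted p = 0.432 with an estimated correlation). RPL16A fell from 478 ± 10.9 to 166 ± 1.41 CPM (-1.52 ± 0.05), RPL9A from 350.2 ± 14.1 to 122 ± 7.19 CPM and RPS28B from 28.5 ± 2.02 to 10.5 ± 2.43 CPM; many of these genes have a near-identical paralog, so the split of reads within a pair is uncertain. The pair RPL41A and RPL41B, with -0.33 and -0.23, did not pass. All 45 ribosome biogenesis genes fell (median -1.19), among them the RNA helicase genes DBP2 (160.5 ± 29.7 to 33.0 ± 1.38 CPM) and HAS1 (142 ± 16.4 to 38.1 ± 1.57 CPM) and the nucleolin gene NSR1 (191 ± 16.6 to 46.4 ± 1.88 CPM). Ribosome biogenesis as a list had camera adjusted p = 3.4e-14 for standing below other genes, and adjusted p = 0.432 with an estimated correlation. In the list of mitochondrial ribosomal protein genes, also drawn by a name pattern, 62 of 66 members fell and 1 rose, with a median of -0.67. Mitochondrial ribosomal proteins as a list stood below the other genes tested (camera adjusted p = 4.69e-13), a call lost at adjusted p = 0.432 with an estimated correlation. The member that rose was MRP8 (474 to 557 CPM, 0.23), whose protein is of unknown function despite its name. Without it 62 of 65 genes fell and 0 rose, with a median of -0.67 (camera adjusted p = 1.26e-13, and adjusted p = 0.432 with an estimated correlation). RSM26 fell from 100.0 ± 3.52 to 38.5 ± 1.51 CPM, MRPL6 from 132 ± 4.39 to 55.7 ± 5.23 CPM and MRPL8 from 221 ± 6.26 to 96.1 ± 2.61 CPM.

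**Figure D2:**
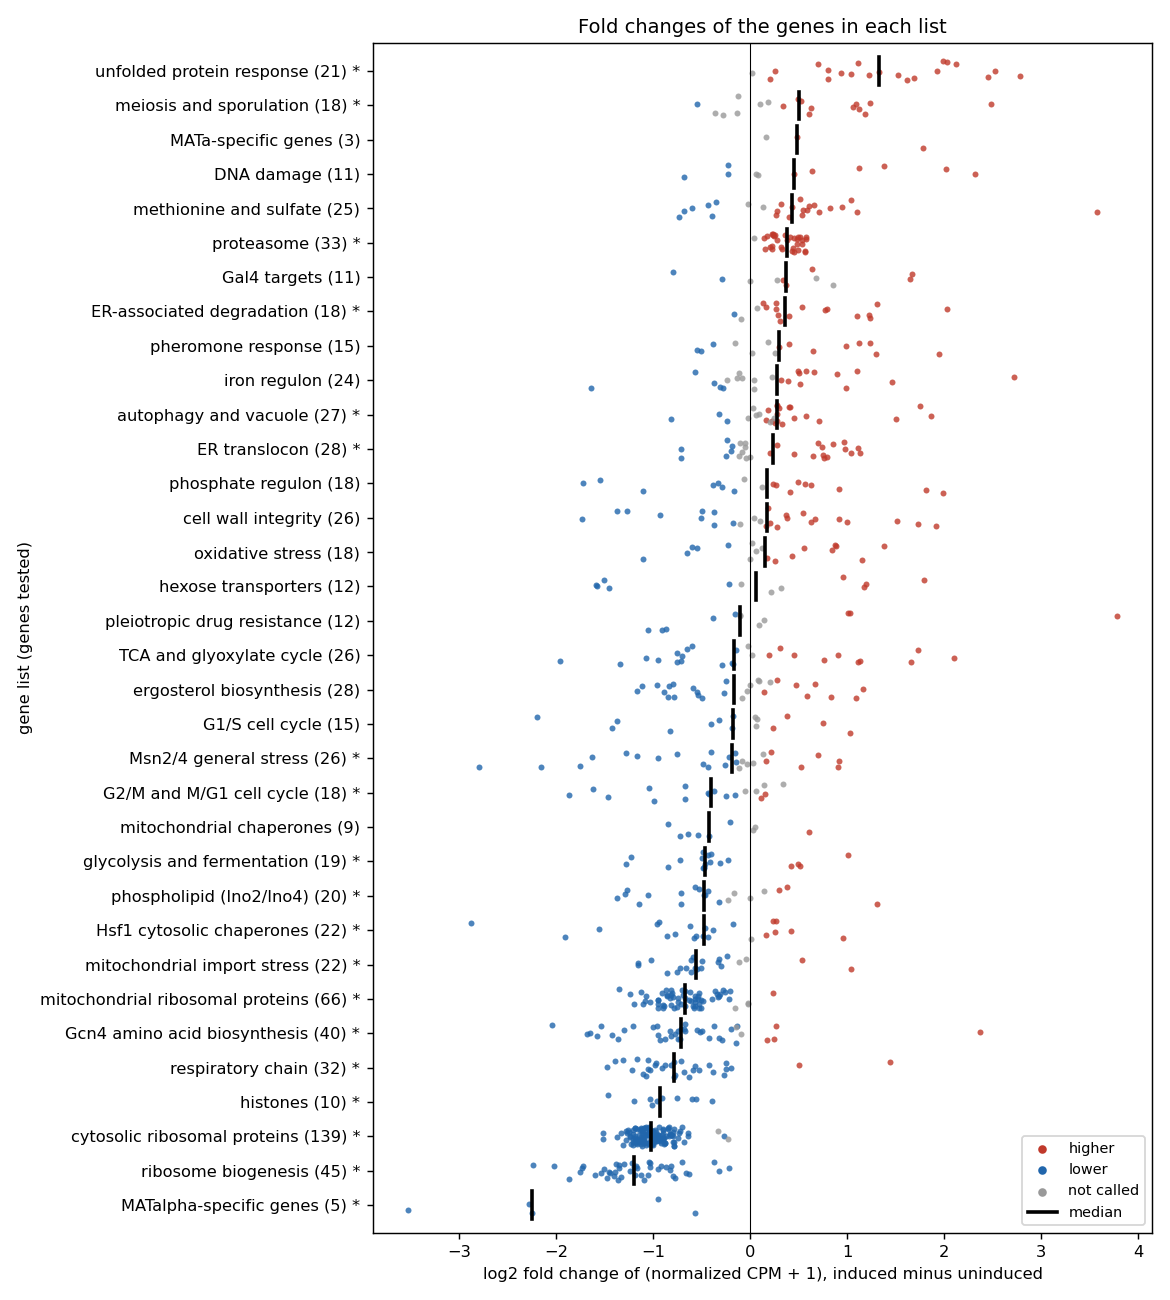
Log2 fold change (x axis, induced minus uninduced) of each gene in the 34 lists (y axis, with the number of genes tested), 1 point per gene, red where higher, blue where lower and grey where not called. Black bars are list medians, from -2.25 for the MATalpha-specific genes to 1.32 for the unfolded protein response, and an asterisk marks the 19 lists called by camera with its preset correlation.

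Genes of the respiratory chain, of mitochondrial import and of glycolysis were mostly lower. Of 32 respiratory chain genes, 30 fell and 2 rose (median -0.78). By camera the respiratory chain list stood below other genes at adjusted p = 1.13e-07, but had adjusted p = 0.432 with an estimated correlation. The cytochrome c1 gene CYT1 fell from 374 ± 19.1 to 134 ± 1.79 CPM and the Rieske protein gene RIP1 from 272 ± 7.85 to 103 ± 4.05 CPM, while ATP20, a subunit of the ATP synthase, rose from 98.9 ± 5.46 to 271 ± 15.3 CPM. In the mitochondrial import list 18 of 22 genes fell and 2 rose (median -0.56), with TOM20 at -1.16, PAM18 at -1.15 and MSP1, an ATPase that extracts misplaced membrane proteins, rising from 96.0 to 199 CPM. The mitochondrial import stress list had camera adjusted p = 0.000695 for standing below other genes, and adjusted p = 0.432 with an estimated correlation. Glycolysis and fermentation genes fell in 15 of 19 members and rose in 4 (median -0.47); TDH1 fell from 2945 ± 11.4 to 1217 ± 11.4 CPM and PFK2 from 1254 ± 17.7 to 536 ± 2.24 CPM, and PDC6 rose from 4.73 ± 0.306 to 10.5 ± 0.75 CPM. The glycolysis and fermentation list stood below the other genes tested (camera adjusted p = 0.0327), a call lost at adjusted p = 0.587 with an estimated correlation. That call ended in 4 alternatives, among them quantile normalization (median -0.18, adjusted p = 0.132) and the fit without uninduced library 2 (adjusted p = 0.0638), within a range of 0.00184 to 0.587 over its alternatives. The tricarboxylic acid and glyoxylate list went both ways, 10 of 26 higher and 14 lower, with a median of -0.16 and a mean of 0.0029: CIT3 (2.10) and IDP2 (1.73) rose. Camera gave the tricarboxylic acid list adjusted p = 0.441, and adjusted p = 0.709 with an estimated correlation. Hexose transporter genes also split, 4 of 12 higher and 5 lower (median 0.06, mean -0.07 and a downward camera test), and their median was -0.08 after quantile normalization. The hexose transporter list did not pass camera, with adjusted p = 0.78, and adjusted p = 0.82 with an estimated correlation. HXT4 fell from 2140.3 ± 80.8 to 713 ± 20.5 CPM and HXT6, nearly identical to HXT7, from 3523 ± 53.2 to 1178 ± 34.2 CPM, and HXT9 rose from 2.11 ± 0.00312 to 9.79 ± 0.854 CPM.

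Amino acid synthesis genes controlled by Gcn4 fell in 34 of 40 members and rose in 4 (median -0.72). The Gcn4 list stood below the other genes tested (camera adjusted p = 5.24e-08). With an estimated correlation it had adjusted p = 0.432, although the estimate, -0.0233, was below the preset 0.01. Correlation between its genes is thus not what ended this call. LYS20 of lysine synthesis fell from 372 ± 10.9 to 89.7 ± 3.37 CPM and LEU9 of leucine synthesis from 94.9 ± 3.03 to 28.9 ± 0.855 CPM, against a rise of SER3 of serine synthesis from 227 ± 3.96 to 1173 ± 17.2 CPM. Methionine and sulfate genes rose in 17 of 25 members and fell in 6, with no call of the list (median 0.43); after SUL1, the sulfhydrylase gene MET17 (549 to 1182 CPM) and the sulfite reductase gene MET10 (93.0 to 192 CPM) rose most. Camera gave the methionine and sulfate list adjusted p = 0.0551, and adjusted p = 0.709 with an estimated correlation. This list passed in 6 alternatives, without uninduced library 1 (adjusted p = 0.0047) and without induced library 2 (adjusted p = 0.0429) among them, with adjusted p between 0.0047 and 0.709 over them all. Phospholipid genes of the Ino2 and Ino4 regulon fell in 13 of 20 members and rose in 3 (median -0.47). The phospholipid list had camera adjusted p = 0.0105 for standing below other genes, and adjusted p = 0.558 with an estimated correlation. The phosphatidylserine synthase gene CHO1 fell from 763 ± 2.02 to 295 ± 18.7 CPM and the desaturase gene OLE1 from 684 ± 82.7 to 278 ± 7.08 CPM, and INO1, the inositol synthase gene, rose from 332 ± 9.70 to 827 ± 80.4 CPM. Ergosterol genes showed no list call, with 8 of 28 higher and 14 lower (median -0.16): ERG25 (-1.17) and ERG4 (-1.11) fell and ERG10 (1.16) rose. The ergosterol biosynthesis list did not stand apart from other genes (camera adjusted p = 0.325, and adjusted p = 0.779 with an estimated correlation).

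Autophagy and vacuolar protease genes rose in 18 of 27 members and fell in 3 (median 0.27). By camera the autophagy and vacuole list stood above other genes at adjusted p = 0.00557, but had adjusted p = 0.465 with an estimated correlation. The vacuolar protease gene PRB1 rose from 1417 ± 41.2 to 5148 ± 162 CPM, the mannosidase gene AMS1 from 149 to 505 CPM and the scaffold gene ATG17 from 36.3 ± 1.03 to 105 ± 5.97 CPM. Iron regulon genes were higher in 12 of 24 members and lower in 5, without a list call (median 0.28). The iron regulon list did not pass camera, with adjusted p = 0.158, and adjusted p = 0.642 with an estimated correlation. TIS11, an mRNA-binding regulator of iron use, rose from 11.3 ± 2.26 to 79.3 ± 3.91 CPM and the siderophore transporter gene ARN2 from 29.4 ± 1.06 to 82.9 ± 2.56 CPM, but FET3 of reductive iron uptake fell from 126 ± 9.92 to 40.1 ± 5.14 CPM. Of 18 phosphate genes, 9 rose and 7 fell (median 0.18); PHM6 (1.99) and PHO89 (1.82) rose and PHO84 (-1.72) fell. The phosphate regulon list did not stand apart from other genes (camera adjusted p = 0.637, and adjusted p = 0.709 with an estimated correlation). In the cell wall list 14 of 26 rose and 9 fell (median 0.17), YLR194C from 459 ± 21.3 to 1734 ± 38.6 CPM and YPS3 from 152 ± 2.22 to 507 ± 7.35 CPM, with CWP1 falling from 323 ± 4.20 to 96.8 ± 1.01 CPM. Camera gave the cell wall integrity list adjusted p = 0.3, and adjusted p = 0.709 with an estimated correlation.

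All 10 histone genes fell (median -0.93), HTB2 from 284 ± 11.4 to 102 ± 0.936 CPM, HTA2 from 172 ± 5.04 to 74.6 ± 0.881 CPM and HTB1 from 856 ± 46.1 to 417 ± 11.6 CPM. The histone list had camera adjusted p = 9.7e-05 for standing below other genes, and adjusted p = 0.432 with an estimated correlation. Cell cycle genes of G2/M and M/G1 fell in 12 of 18 members and rose in 2 (median -0.40). DSE2 (581 to 158 CPM), DSE1 (241 to 78.0 CPM) and EGT2 (893 to 323 CPM), which act in daughter cell separation, led the falls. The G2/M and M/G1 list stood below the other genes tested (camera adjusted p = 0.0142), a call lost at adjusted p = 0.432 with an estimated correlation. The G1/S list was not called, with 8 of 15 lower and 4 higher (median -0.17): HO (-2.20), RNR1 (-1.37) and CLB6 (2.79 ± 0.59 to 0.404 ± 0.117 CPM, -1.43) fell. Camera gave the G1/S list adjusted p = 0.528, and adjusted p = 0.709 with an estimated correlation. Among DNA damage genes 6 of 11 rose and 3 fell, also without a list call (median 0.45), and the ribonucleotide reductase genes RNR2 (382 to 1549 CPM) and RNR3 (11.6 to 31.7 CPM) and HUG1 (3.28 to 20.2 CPM) rose. The DNA damage list did not pass camera, with adjusted p = 0.0977, and adjusted p = 0.587 with an estimated correlation. Against other genes the DNA damage list passed in 3 alternatives, without uninduced library 1 (adjusted p = 0.0271) among them, with adjusted p from 0.0209 to 0.587. Meiosis and sporulation genes rose in 11 of 18 members and fell in 1 (median 0.51), HOP1 from 9.58 ± 1.34 to 58.1 ± 3.46 CPM, DMC1 from 4.78 ± 0.235 to 12.6 ± 1.01 CPM and SPS1 from 3.25 ± 0.219 to 8.66 ± 0.617 CPM. The meiosis and sporulation list stood above the other genes tested (camera adjusted p = 0.0494), a call lost at adjusted p = 0.432 with an estimated correlation. That call ended in 11 alternatives, among them leaving out uninduced library 2 (adjusted p = 0.0673) or induced library 2 (adjusted p = 0.0569), within a range of 0.0292 to 0.432 over the alternatives against other genes.

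Markers of mating type served as a check on the cells cultured. All 5 MATalpha-specific genes tested fell, with a median of -2.25. By camera the MATalpha-specific list stood below other genes at adjusted p = 0.0012, but had adjusted p = 0.432 with an estimated correlation. MF(ALPHA)1, the main alpha-factor gene, fell from 1897 ± 17.3 to 399 ± 14.7 CPM and SAG1, the alpha-agglutinin gene, from 372 ± 11.1 to 76.1 ± 2.67 CPM. Of the MATa-specific genes 3 were expressed highly enough to test, and BAR1 (4.58 ± 0.237 to 18.2 ± 0.875 CPM) and STE6 (40.5 ± 1.77 to 57.0 ± 1.09 CPM) rose (median 0.48). The MATa-specific list did not pass camera, with adjusted p = 0.158, and adjusted p = 0.465 with an estimated correlation. The a-factor genes MFA1 and MFA2 stayed under 1 CPM in each library. Pheromone response genes rose in 8 of 15 members and fell in 3, without a list call (median 0.30), with PRM2 rising from 2.89 ± 0.45 to 13.9 ± 0.495 CPM, PRM3 from 0.331 ± 0.184 to 2.25 ± 0.0849 CPM and PRM4 from 25.7 ± 2.90 to 61.6 ± 3.57 CPM. The pheromone response list did not stand apart from other genes (camera adjusted p = 0.166, and adjusted p = 0.465 with an estimated correlation).

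LEU2 (chromosome III, 91324 to 92418), the integration site of the construct, fell from 6.52 ± 0.274 to 0.727 ± 0.12 CPM (-2.12 ± 0.19, adjusted p = 4.16e-07), that is from 96 and 67 reads to 10 and 10. The level of the IAPP transgene was not analysed here, so induction rests on the labels. Targets of Gal4, the activator of galactose genes, were not called as a list, with 5 of 11 higher and 2 lower (median 0.37). Camera gave the Gal4 target list adjusted p = 0.271, and adjusted p = 0.587 with an estimated correlation. Without induced library 2 it passed (adjusted p = 0.0498, with a range of 0.0498 to 0.587 over its alternatives). GAL80, which encodes the repressor of Gal4, rose from 87.6 ± 2.58 to 137 ± 2.97 CPM (0.64 ± 0.06, adjusted p = 4.09e-07), and GCY1 (0.37) and MTH1 (0.34) rose too. The values of GAL1, GAL2 and GAL10 rested on 1 library. GAL1 was at 8.90 and 12.4 CPM uninduced and 33.0 and 9.06 CPM induced (0.68 ± 0.38, adjusted p = 0.129), and without induced library 1 its log2 fold change was -0.20 (adjusted p = 0.415, with a range of 3.04e-05 to 0.555 over its alternatives). GAL1 passed as higher in 5 alternatives, among them edgeR (0.98, adjusted p = 0.0434) and the fits without uninduced library 2 (0.90, adjusted p = 0.0038) and without induced library 2 (1.56, adjusted p = 3.04e-05). GAL2 (1.67 ± 0.61, adjusted p = 0.0262) and GAL10 (1.64 ± 0.50, adjusted p = 0.00996) were called, but without induced library 1 they were at 0.33 (adjusted p = 0.497) and 0.50 (adjusted p = 0.122), within ranges of 9.77e-10 to 0.497 and 4.88e-12 to 0.313. These calls also ended after quantile normalization, without a variance trend, with a robust variance prior and with DESeq2 on the recovered reads (2.81 and 2.31), and that of GAL2 against a 1.2-fold change. The uracil permease gene FUR4 fell from 24.8 ± 1.07 to 13.9 ± 0.316 CPM.

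Of the 34 lists, 19 were called with the preset correlation, 6 higher and 13 lower, and 0 with an estimated correlation (2 at an unadjusted p under 0.05). In contrast fry, which does not compare a list with other genes, called 31. Counts of members adjusted over the list alone equalled those given in each list except the mitochondrial ribosomal proteins, where 63 fell. With 2 libraries per group an exact permutation test cannot give a p under 0.333, so each call rests on the spread that limma shares across genes. Medians of several lists moved by over 1.5 times with the setting. With total-count scaling, which moves the median of all genes to 0.12, they were -0.04 for ergosterol biosynthesis, -0.04 for the tricarboxylic acid list, -0.05 for G1/S, -0.06 for Msn2/4, 0.27 for oxidative stress, 0.29 for the phosphate regulon, 0.30 for cell wall integrity, 0.36 for the ER translocon and 0.16 for hexose transporters. Quantile normalization gave -0.07 for ergosterol biosynthesis, -0.05 for the tricarboxylic acid list, 0.31 for oxidative stress, 0.18 for the iron regulon, 0.08 for the phosphate regulon, 0.30 for cell wall integrity and 0.19 for pheromone response. With a minimum of 10 CPM the phosphate regulon was at 0.08, G1/S at -0.06, pheromone response at 0.18 and hexose transporters at -0.22, and with no filter ergosterol biosynthesis was at -0.08. Without induced library 2 the ER translocon was at 0.16, the tricarboxylic acid list at -0.11 and DNA damage at 0.28. Without induced library 1 cell wall integrity was at 0.11, without uninduced library 1 pleiotropic drug resistance was at -0.07, and without uninduced library 2 pheromone response was at 0.19. The hexose transporter median ran from -0.22 to 0.19 over its alternatives.

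The size of change in genes of low level depended on the pseudocount. Named genes that moved by over 1.5 times with 5 CPM, as a log2 value or as a fold, kept their direction. Higher genes among them were AMF1 at 3.78, OPI9 at 3.40, SLZ1 at 3.04, RTA1 at 2.87, SUL1 at 2.83, HUG1 at 1.61, PRM2 at 1.26, PRM3 at 0.44, HXT9 at 1.06, PHM6 at 1.27, PHO89 at 1.14, SPS1 at 0.73 and GAL2 at 0.94. Lower genes were YDR222W at -3.09, MF(ALPHA)2 at -2.94, PHO84 at -1.13, LEU2 at -1.01, CLB6 at -0.53 and SRX1 at -0.70. With 0.25 CPM the moves were to -2.80 for LEU2, -2.21 for CLB6 and 2.14 for PRM3. For these 3 genes edgeR gave -3.15, -2.75 and 2.64, and DESeq2 -3.17, -2.80 and 2.70.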

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

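The read limits used in this part were chosen after the data were seen. For a mean under 1 CPM, 745 rows were left out of the comparison. Of these, 22 had at most 3 reads over the uninduced pair and more than 3 reads in each induced library. That they lie above the uninduced level follows from these limits. The mirror image, at most 3 reads over the induced pair and more than 3 in each uninduced library, held for 8 rows. The highest of the 22 was YIR020C-B, with 30 reads over the induced pair against 3 over the uninduced pair, and YDL022C-A had 24 reads against 3. YLR366W had 22 reads over the induced pair, 8 and 14 per library, and 0 over the uninduced pair. No explanation was tested for these rows.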

How the results depend on the processing

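Scaling to total reads, the crossed block, the test against a 1.2-fold change the lists without shared members and those without RPP1 and MRP8 were chosen after seeing the data. The count of changed genes stayed between 3822 and 4512 over the alternatives that keep the test against no change, with 4388 under median-of-ratios scaling, 4331 after quantile normalization and 3911 to 4228 with 1 library left out, where the lone library is assumed to vary like the pair. Against a 1.2-fold change it was 2685, with 1286 higher and 1399 lower; this test asks for a larger change by construction. Lists called by camera went from 19 to 0 with an estimated correlation (2 at an unadjusted p under 0.05) and to 31 with fry, which by construction does not compare a list with other genes. The estimated run had few degrees of freedom, so its loss of calls does not measure correlation between genes. Over the other alternatives 16 to 21 lists were called. At an adjusted p under 0.01 in the authors' deposited table, 1947 of 1947 genes kept were called here in the same direction, while 1858 genes called here had an adjusted p of 0.05 or more there. Of 2273 alternative values for the 127 named genes, 2253 kept direction and side of the threshold, 12 lost the call, 7 gained it and 1 reversed. Of 747 values for the 34 lists, 672 kept both, 47 lost the call, 22 gained it and 6 reversed. The medians that reversed were those of Msn2/4 general stress (0.0178 after quantile normalization), pleiotropic drug resistance (0.0181 with total-count scaling) and the list hexose transporters (-0.0034 with a pseudocount of 5 CPM, -0.217 with a minimum of 10 CPM, -0.0751 after quantile normalization, and -0.0230 to 0.0788 with 1 library left out). GAL1 ranged from -0.197 to 1.56 with 1 library left out. The cause of these reversals was not tested, except that GAL1 turns on induced library 1.

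The labels do not say that replicate numbers pair the cultures, and deviations of same-numbered libraries correlated at -0.136 across the genes kept and -0.009 across those with 20 CPM or more. With the replicate block 4512 genes were called, 2219 higher and 2293 lower, and 19 lists. The block gave GAL1 a call (adjusted p = 0.0409, within 3.04e-05 to 0.555 over its alternatives) and the list methionine and sulfate (0.0255, within 0.0047 to 0.709), ended that of the list meiosis and sporulation (0.0553, within 0.0292 to 0.432), and changed no other call of a named gene or list. With the numbers crossed 4399 genes were called, and of named genes and lists 1 gene and 2 lists gained a call and 2 lists lost it. Depth limits the low end: 1 read was worth 0.0642 to 0.100 CPM, and of the genes under 1 CPM no call is given.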

Other observations

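The 10 lists in this part, the genes named from them and the tests on estradiol, on genes of like coding length and GC content, on mating type and on MATALPHA1 were chosen after the results were seen. Adjusted p-values of these lists cover the 10 lists alone. Since the lists were chosen on the same values, their p-values are a description and not a test. Genes of the secretory pathway beyond the fixed lists rose with the unfolded protein response. Of 32 genes of N- and O-glycosylation, 21 rose and 3 fell (median 0.39), with PMT3 at 1.90 and GFA1 at 1.62. The glycosylation list had camera adjusted p = 6.42e-05 for standing above other genes, and adjusted p = 0.372 with an estimated correlation. Coat and cargo genes of COPII vesicles, which leave the ER, rose in 19 of 23 members and fell in 2 (median 0.65), with ERV29 at 1.75. The COPII list stood above the other genes tested (camera adjusted p = 3.94e-05), a call lost at adjusted p = 0.307 with an estimated correlation. Genes of COPI vesicles, which return to the ER, rose in 14 of 19 members and fell in 0 (median 0.25). By camera the COPI list stood above other genes at adjusted p = 0.000997, but had adjusted p = 0.372 with an estimated correlation. GPI anchor synthesis genes rose in 14 of 25 and fell in 4 (median 0.26), with MCD4 at 2.53. The GPI anchor synthesis list had camera adjusted p = 0.0172 for standing above other genes, and adjusted p = 0.505 with an estimated correlation.

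Translation factors and tRNA synthetases fell with the ribosomal protein genes. Initiation and elongation factor genes fell in 28 of 32 members and rose in 3 (median -0.77), and aminoacyl-tRNA synthetase genes fell in 18 of 19 and rose in 1, CDC60 (median -0.70). By camera the tRNA aminoacylation list stood below other genes at adjusted p = 1.06e-05, but had adjusted p = 0.429 with an estimated correlation. The translation initiation and elongation list stood below the other genes tested (camera adjusted p = 4.58e-07), a call lost at adjusted p = 0.429 with an estimated correlation. Thiamine genes rose in 14 of 18 members and fell in 1, the transporter gene THI7 (median 1.21); THI5, THI11, THI12 and THI13 are near-identical, so their separate values are uncertain. The thiamine synthesis list had camera adjusted p = 0.000163 for standing above other genes, and adjusted p = 0.307 with an estimated correlation. Genes under nitrogen catabolite repression fell in 16 of 25 members (17 when adjusted over the list alone) and rose in 6 (median -0.44), with MEP2 at -2.75, GAP1 at -2.45 and DAL4 at 2.61. The nitrogen catabolite repression list stood below the other genes tested (camera adjusted p = 0.0172), a call lost at adjusted p = 0.505 with an estimated correlation. Zinc regulon genes went both ways, 5 of 14 higher and 7 lower (median -0.08). Camera gave the zinc regulon list adjusted p = 0.469, and adjusted p = 0.657 with an estimated correlation.

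The fall of cytosolic ribosomal protein genes was set against the scaling of the libraries and against coding length and GC content. Over the authors' scaling and 3 others, the highest median of the list was -0.887 (-0.89 without RPP1, which is not a ribosomal protein). The fall relative to other genes was thus kept under each scaling tried. These scalings moved the median of all genes to 0.12 at most, so they could hardly have removed the fall. All are relative, so a change in total mRNA per cell was not tested. Against coding length and GC content as the cause, 649 other genes of like coding length and GC content had a median of -0.0560 (quartiles -0.44 and 0.31), above the list's quartiles of -1.12 and -0.90. A fitted trend in both explained 0.256% of the variance of other genes, so the residual median of -1.02 after it adds nothing. An effect of estradiol without IAPP cannot be told apart from that of IAPP, since 0 libraries had estradiol and no IAPP gene, so both stay open as causes and the biological one was not tested.

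The fall of MATalpha-specific genes (median -2.25) was kept under 4 scalings, with -1.95 as the highest median. These relative scalings differ too little to have removed a fall of this size, so they do not test scaling as a cause. Diploid cells would lower haploid-specific genes, and cells of mating type a would raise MATa-specific ones. The 14 haploid-specific genes had a median of -0.198 (quartiles -0.66 and 0.03). The 13 without HO, left out of this list after its fall was seen, had -0.18, with 7 lower and 3 higher (camera adjusted p = 0.211, and adjusted p = 0.429 with an estimated correlation). The 3 MATa-specific genes had a median of 0.48, and the a-factor gene MFA1 reached 0.650 CPM at most. The fall of HO (-2.20), a haploid-specific gene also in the G1/S list, goes with diploid cells. The rises of BAR1 (4.58 to 18.2 CPM) and STE6 (40.5 to 57.0 CPM) go with cells of mating type a. The means of MFA1 (0.166 to 0.646 CPM), MFA2 (0.215 to 0.347 CPM), ASG7 (0.182 to 0.768 CPM) and AGA2 (0.182 to 0.323 CPM) also rose, on few reads and untested. STE2 (5.49 to 6.25 CPM) was not called. A small share of either kind of cell is therefore not excluded. The alpha-specific median, however, was a fall to 0.211 of the uninduced level, which a small share could not give alone. The haploid-specific genes as a set argue against diploid cells as the source of the whole fall. For cells of mating type a, the low MFA1 and the uncalled STE2 give no sign of a large share. MATALPHA1 and its silent copy, which share reads, together went from 55.2 ± 1.30 to 32.8 ± 3.42 CPM, a log2 change of -0.74. A candidate explanation is a lower level of this activator of alpha-specific genes, a hypothesis drawn from these same values and without an independent test. Cells of mating type a or diploid cells could lower MATALPHA1 too, so its fall alone does not tell these explanations apart.

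Dubious open reading frames that overlap another gene moved with it in part, so reads of the overlapped gene may account for some of their calls (133 of 301 dubious frames kept were called). Across 128 pairs Pearson's r of the log2 fold changes was 0.477 and Spearman's rho 0.571 (permutation p = 1e-05, the smallest the permutations can give; 0.431 without the 2 farthest pairs), a value between the bounds set for and against this source. In 16 pairs on the same strand r was 0.954, above the bound set for this source. In 112 pairs on opposite strands it was 0.361, between the bounds. The bounds were set for all pairs together. Pairs are genes, not independent replicates. OPI9 is a case where the overlapped gene moved far less, with 4.38 against 0.46 for VRP1.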
